A study of Mus musculus with 24 samples.

How the data were processed

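Messenger RNA was measured in 24 mouse liver samples, 8 per group, 20 weeks after surgery. The groups, taken from the labels alone, were sham surgery (Sham), Roux-en-Y gastric bypass (RYGB) and weight matching by calorie restriction (WM). Libraries keep the sample numbers of the labels. Per the labels' protocols, livers were frozen in liquid nitrogen, RNA was taken up in Trizol and cleaned on RNeasy columns, and libraries came from the QuantSeq kit, which primes from the 3′ end of messenger RNA, and were read for 50 bp in the forward direction. These hold about 1 fragment per transcript, so counts were not divided by gene length. Priming at the poly(A) tail can also start inside a transcript, and genes with a misplaced 3′ end can lose reads.

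The authors deposited 2 tables of the same 14995 genes. The raw table holds whole-number counts of reads per Ensembl gene, and the smallest mean count of any gene in this deposited table is 3. The second deposited table holds a normalized signal, each raw count divided by 1 size factor per library. Recomputed median-of-ratios factors gave those values to within a relative difference of 5e-15. The submitters' processing notes name DESeq2 1.34 and R 4.1.2. Aligner, counting program, genome build, annotation, strand setting and treatment of reads matching several genes are not given in the sources used here. The raw counts were used for all tests but 1 alternative.

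Genes were named by Ensembl ID through GENCODE M21 (GRCm38), which holds 14959 of them. Of 13343 genes with a start in both, the deposited start equals that of GENCODE M21 for 326, so that the deposited coordinates were not used. Library totals were 13659647 to 22766612 counts, and 13714 to 14813 genes had at least 1 count. Pairs of libraries of 1 group differed by a chi-square of 26.4 to 578 per degree of freedom, so that none was a duplicate.

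Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the groups (13121 genes), library sizes were scaled by TMM, and a quasi-likelihood model was fitted to the 24 libraries together with no covariate (common biological coefficient of variation 0.398, prior degrees of freedom 7.91). The 3 differences of group means were tested with the quasi-likelihood F-test and adjusted by Benjamini-Hochberg over all tested genes, and calls have an adjusted p under 0.05. A TMM-scaled CPM assumes that most genes do not change. Lists of genes were tested with camera in limma 3.58.1, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 35 of 39 lists with at least 5 tested members, and again with a correlation estimated for each list. The lists, 866 genes of liver metabolism, signalling, liver cell types and other tissues, came from textbook knowledge, and 43 genes stand in more than 1. The groups, comparisons, tests, lists, rule for named genes and the first set of alternatives were fixed before the data were examined.

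Genes were named by a rule. For each comparison it took the 5 higher and 5 lower called genes with the largest fold change, with a mean of at least 5 CPM in 1 of the groups, at least 7 of the 8 libraries of the first group beyond the median of the other, and no predicted gene or clone. It also took the 2 called members with the smallest p from each of the 10 lists with the highest share of called members, and Cyp7a1, Cyp8b1, Fgf21 and Cidec. Some of the genes taken are not reported here. A gene with no count in a group was given as a bound against 3 counts over the group. Single measures of libraries were compared by two-sided exact permutation tests of 8 against 8, adjusted by Benjamini-Hochberg, and correlations over 8 libraries by exact permutation of pairings.

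The first set of alternatives held DESeq2 1.42.0, RLE scaling, no low-count filter, a filter of 1 CPM in 8 libraries, a fit of the compared groups alone, limma-voom with quality weights, limma-trend on log2 of the deposited normalized values plus a pseudocount of 1, a minimum absolute log2 fold change of 1, each library left out in turn, the estimated correlation for lists and separate Sham libraries for the overlap. Chosen after seeing the data were scaling by library totals, a correction of each library for smooth trends on GC content and transcript length (mgcv 1.9.3), the share of counts on Gm42418 as a covariate, and leaving out the 3 libraries with pancreas transcripts (Sham 17, RYGB 18 and RYGB 19), alone or with WM 25. The same settings were then also applied to the list tests and to the overlap.

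The procedure was tested on simulated data with genes changed by known folds. In RYGB vs Sham (12779 genes) edgeR recovered 10.4% of the 1.5-fold, 61.2% of the 2-fold and 92.4% of the 4-fold changes with 2.68% false calls, in WM vs Sham (12851 genes) 4.48%, 44.8% and 90.9% with 5.10% false, and in RYGB vs WM (12781 genes) 11.9%, 52.2% and 90.9% with 2.83% false. DESeq2 made 12.2%, 13.1% and 13.8% false calls in the same simulations. A raised list was found in each comparison and 0 of 34 unchanged lists were called, with genes drawn independently of each other, which those of a tissue need not be. A length trend put into 1 group gave 7, 7 and 19 false genes, in the same order, and 0 after the correction.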

Results

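Liver RNA was counted in 24 mouse libraries, 8 from each of 3 groups, all collected 20 weeks after surgery. RYGB stands for Roux-en-Y gastric bypass, a weight-loss operation that reroutes food past most of the stomach and the upper small intestine. Sham stands for mice given a sham operation. WM stands for mice kept at the weight of the RYGB mice by restricting their calories. Each library was made from the 3′ ends of messenger RNA and read 50 bp from 1 end. Counts assigned to the 14995 genes of the table summed to 13659647 to 17391377 in Sham, 14208021 to 22766612 in WM and 14002193 to 19958019 in RYGB. Of these genes, 13121 had enough counts to be tested. Gene levels are counts-per-million (CPM) values with library sizes scaled by TMM, given as mean ± SD (n = 8 in each group), a log2 fold change is given ± its standard error, and the median of a list is that of the log2 fold changes of its tested genes, given with the adjusted p of the list test, and members not counted as risen or fallen did not pass.

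Transcripts of pancreatic acinar cells, which make digestive enzymes, appeared in 3 libraries, called acinar here. Summed over 17 acinar genes outside the genes tested, among them the proteases Prss2 and Cpa1, they reached 1887 CPM in Sham 17, 2516 CPM in RYGB 18 and 2872 CPM in RYGB 19. The other 21 libraries held at most 28.2 CPM. Log2 CPM, less each gene's mean over libraries, was fitted on log2 transcript length. Slopes were 0.149 ± 0.0428 in Sham, -0.0924 ± 0.0657 in WM and -0.0567 ± 0.0629 in RYGB (n = 8 each). Both differences from Sham had p = 0.000155 in a two-sided exact permutation test, the smallest it can give, and adjusted p = 0.000932 over 12 added tests. No difference between groups in library totals, genes detected, mitochondrial shares or the share of the 10 most abundant genes passed adjustment.

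After RYGB, genes of cholesterol synthesis (19 of 25 rose) and mitochondrial respiration (33 of 45) were higher than in Sham as lists (adjusted p = 0.0146 and 0.0402 with an estimated correlation). With the preset correlation of the list test alone, higher calls went to genes higher in males than in females (14 of 20 rose) and Kupffer cell markers (12 of 20), and lower calls to matrix (15 of 41 fell), lipid droplet (8 of 24), fat synthesis (9 of 28) and interferon genes (9 of 30), all 6 lost otherwise (adjusted p = 0.133 to 0.638 with an estimated correlation). Hsd3b5, a male-biased hydroxysteroid dehydrogenase, rose from 0.167 ± 0.251 to 54.6 ± 38.1 CPM (log2 fold change 8.25 ± 0.72, adjusted p = 3.89e-09). Slco1a1, a hepatocyte uptake transporter for organic anions, rose from 4.02 ± 5.89 to 216 ± 69.8 CPM (log2 fold change 5.74 ± 0.58, adjusted p = 5.38e-08). Cidec, a protein that enlarges lipid droplets, fell from 59.8 ± 28.1 to 2.43 ± 2.14 CPM (log2 fold change -4.61 ± 0.50, adjusted p = 2.03e-07). Cyp2b13, a female-biased cytochrome P450, stood at 13.7 ± 10.6 CPM in Sham and had no count in any RYGB library, which makes it at least 577-fold lower against a floor of 3 counts over the group, a floor that covers counting error only (adjusted p = 1.05e-07).

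The largest rises among the genes named by rule also took in Tff3, a secreted mucosal trefoil peptide, at 14.4 ± 10.8 CPM in RYGB and 0.363 ± 0.286 CPM in Sham (log2 fold change 5.30 ± 0.62, adjusted p = 6.88e-07), the lectin-like receptor gene Clec2h (log2 fold change 4.97, adjusted p = 3.04e-10) and the male-biased fatty acid hydroxylase Cyp4a12b (log2 fold change 4.82, adjusted p = 3.04e-06). The largest falls took in Sprr1a, a small proline-rich protein of squamous epithelia, at 0.0743 ± 0.155 CPM in RYGB and 14.2 ± 5.97 CPM in Sham (log2 fold change -7.48 ± 0.56, adjusted p = 4.69e-10). Ly6d, a surface protein of the Ly6 family, fell from 216 ± 82.3 to 4.73 ± 4.44 CPM (log2 fold change -5.51 ± 0.54, adjusted p = 4.19e-08), and Ephb2, a receptor kinase for ephrins, also fell (log2 fold change -5.06, adjusted p = 4.23e-06). Each of these 10 genes lay beyond the Sham median in 8 of 8 RYGB libraries. Fgf21, a fasting and stress hormone of the liver, fell from 5.41 ± 1.47 to 1.26 ± 0.572 CPM (log2 fold change -2.10 ± 0.40, adjusted p = 0.000349). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 48.6 ± 35.9 CPM in RYGB and 51.6 ± 34.5 CPM in Sham (log2 fold change -0.09, adjusted p = 0.909), and Cyp8b1, which sets the share of cholic acid, at 489.8 ± 243 CPM in RYGB and 416 ± 189 CPM in Sham (log2 fold change 0.24, adjusted p = 0.727), and neither passed.

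Of 25 genes of cholesterol synthesis and uptake, 19 rose and 0 fell, while 20 rose and 0 fell adjusted over the list alone, with Cyp51 up from 81.9 ± 19.2 to 357 ± 108 CPM and Sqle, the squalene epoxidase, up from 11.1 ± 5.21 to 67.1 ± 17.2 CPM. Cholesterol genes had a median of 1.37 (adjusted p = 1.04e-19, adjusted p = 0.0146 with an estimated correlation). Among 45 nuclear genes of oxidative phosphorylation, 33 rose and 0 fell, and 35 rose and 0 fell adjusted over the list alone, among them Atp5h of the ATP synthase (1.43 on the log2 scale) and Ndufv2 of complex I (0.90). Respiratory genes had a median of 0.76 (adjusted p = 3.29e-17, adjusted p = 0.0402 with an estimated correlation). Respiratory genes have short transcripts, with a median length of 1363 bp against 3229 bp over all genes, and their median was 0.46 after the GC and length correction, with 25 of 45 higher, and 0.43 under library totals. These 2 lists were the only ones of the 20 called in RYGB vs Sham that also passed with an estimated correlation. For the 20 male-biased liver genes, 14 rose and 1 fell, against 16 rose and 1 fell adjusted over the list alone. Elovl3, a fatty acid elongase, rose from 60.5 ± 14.4 to 300.3 ± 78.2 CPM, and the pheromone carrier Mup17 was the 1 that fell (log2 fold change -1.55). Male-biased genes had a median of 1.62 (adjusted p = 1.02e-13, adjusted p = 0.133 with an estimated correlation). Among 13 female-biased liver genes, 6 fell and 2 rose, and 6 fell and 3 rose adjusted over the list alone, with Gstm3, a glutathione transferase, down from 167 ± 90.6 to 25.1 ± 17.9 CPM. Female-biased genes had a median of -0.99 (adjusted p = 0.0119, adjusted p = 0.417 with an estimated correlation). The call was lost under limma-voom or under library totals (adjusted p = 0.107 and 0.0778). Holding Cyp2b13 at its bound left that median at -0.99 and moved the mean from -1.43 to -1.31.

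Of 20 Kupffer cell markers, 12 rose and 0 fell, while 12 rose and 1 fell adjusted over the list alone, with Fcna, a ficolin, up from 6.50 ± 3.10 to 37.9 ± 11.3 CPM and Timd4, a receptor for dying cells, up from 1.03 ± 0.721 to 7.14 ± 6.94 CPM. Kupffer markers had a median of 0.96 (adjusted p = 1.42e-05, adjusted p = 0.219 with an estimated correlation). Among 27 markers of recruited and lipid-associated macrophages, 10 fell and 4 rose, and 11 fell and 5 rose adjusted over the list alone, where the elastase Mmp12 (-4.11) and the membrane-binding annexin Anxa2 (-2.40) fell and Tyrobp and Lyz2 were among those that rose. Recruited macrophage markers had a median of -0.54 (adjusted p = 0.0119, adjusted p = 0.586 with an estimated correlation). This list did not pass under library totals, without Sham 2 or without Sham 3 (adjusted p = 0.0712, 0.0517 and 0.0551), and the median was -0.31 without Sham 3 and -1.09 without RYGB 22. For the 17 lymphocyte markers, 5 rose and 0 fell, against 9 rose and 1 fell adjusted over the list alone, the called ones being Cd3d (2.11), Igkc (2.65), Ighg2b (2.71), Ighg2c (3.16) and Trbc2 (1.25), which encode T cell receptor and immunoglobulin chains. Lymphocyte markers had a median of 1.56 (adjusted p = 0.0205, adjusted p = 0.582 with an estimated correlation). No list call was made under the 1 CPM filter, after the GC and length correction or without Sham 2 (adjusted p = 0.051, 0.107 and 0.0517). Of 23 endothelial markers, 6 rose and 0 fell, while 6 rose and 0 fell adjusted over the list alone, led by Egfl7 (1.75), Wnt2 (2.02) and Dnase1l3 (1.24). Endothelial markers had a median of 0.55 (adjusted p = 0.000165, adjusted p = 0.337 with an estimated correlation). Among 41 genes of matrix and activated stellate cells, 15 fell and 1 rose, and 21 fell and 1 rose adjusted over the list alone, led by the fibrillar collagens Col1a1 (-3.64), Col1a2 (-2.68) and Col3a1 (-2.12). Matrix genes had a median of -0.81 (adjusted p = 1.54e-07, adjusted p = 0.133 with an estimated correlation). For the 12 erythrocyte markers, 3 rose and 0 fell, against 3 rose and 0 fell adjusted over the list alone, these being Hbb-bs (1.52), Hbb-bt (1.37) and Fech (0.44). Erythrocyte markers had a median of 0.71 (adjusted p = 0.00506, adjusted p = 0.133 with an estimated correlation).

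Among 24 genes of lipid droplets and fatty acid uptake, 8 fell and 1 rose, and 8 fell and 1 rose adjusted over the list alone, including Plin4 (-2.95), Cidea (-3.24) and Cd36 (-1.45) among the falls. Lipid droplet genes had a median of -0.18 (adjusted p = 0.00426, adjusted p = 0.133 with an estimated correlation), against -0.48 after the GC and length correction, -0.33 without the 3 acinar libraries and -0.33 without those 3 and WM 25. Of 28 genes of fatty acid and triglyceride synthesis, 9 fell and 2 rose, while 12 fell and 2 rose adjusted over the list alone, with Mogat1 (-2.53), Scd1 (-1.59), Elovl6 (-1.50) and Fasn (-0.82) among the falls. Fat synthesis genes had a median of -0.49 (adjusted p = 0.00648, adjusted p = 0.417 with an estimated correlation). For the 30 interferon response genes, 9 fell and 0 rose, against 11 fell and 0 rose adjusted over the list alone, with Ifi44 (-2.19), Rsad2 (-1.15) and Ifit1 (-1.63) among them. Interferon genes had a median of -0.54 (adjusted p = 0.00294, adjusted p = 0.638 with an estimated correlation). Among 29 cell cycle genes, 7 fell and 0 rose, and 10 fell and 0 rose adjusted over the list alone, with Ccnd1 (-1.04) and Mki67 (-1.79) among them. Cell cycle genes had a median of -0.93 (adjusted p = 0.000547, adjusted p = 0.219 with an estimated correlation). Of 15 genes of bile acid synthesis, 5 rose and 1 fell, while 6 rose and 1 fell adjusted over the list alone, Cyp2c70 (1.35), Cyp7b1 (1.95), Cyp27a1 (1.16), Akr1c6 (0.96) and Slc27a5 (0.69) being higher and Cyp46a1 (-1.95) lower. Bile acid synthesis genes had a median of 0.36 (adjusted p = 0.00506, adjusted p = 0.133 with an estimated correlation), while the median was -0.014 under library totals. For the 29 targets of the drug receptors CAR and PXR, 9 rose and 3 fell, against 9 rose and 5 fell adjusted over the list alone. The falls were Cyp2b10 (-5.95), Gsta1 (-3.11) and Cyp3a11 (-1.30), of which Cyp2b10 is the classic CAR target, and Cyp2c54 (4.04) led the rises. Drug metabolism genes had a median of 0.25 (adjusted p = 0.0264, adjusted p = 0.417 with an estimated correlation), while the median was -0.10 under library totals. They did not pass without any 1 of Sham 2, RYGB 18 or RYGB 19 (adjusted p = 0.0516 to 0.0756), nor under limma-trend, after the GC and length correction, without the 3 acinar libraries or without those 3 and WM 25 (adjusted p = 0.0688 to 0.249), and the median was 0.16 under limma-voom, 0.12 under limma-trend, 0.09 after the GC and length correction and 0.14 without RYGB 29.

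Of 20 pericentral hepatocyte markers, 10 rose and 0 fell, while 11 rose and 1 fell adjusted over the list alone, with Cyp2e1, a P450 that oxidizes ethanol, up from 1469.6 ± 271 to 4087 ± 656 CPM and Cyp27a1, a sterol hydroxylase, up from 169 ± 48.7 to 378 ± 71.6 CPM. Pericentral markers had a median of 0.63 (adjusted p = 9.6e-05, adjusted p = 0.133 with an estimated correlation). Among 21 periportal hepatocyte markers, 11 rose and 1 fell, and 11 rose and 1 fell adjusted over the list alone, with albumin (Alb) up from 33587 ± 6173 to 81619 ± 15583 CPM and E-cadherin (Cdh1) up from 10.1 ± 2.98 to 45.0 ± 14.4 CPM. Periportal markers had a median of 0.63 (adjusted p = 0.000146, adjusted p = 0.133 with an estimated correlation). For the 26 genes of methionine and folate-dependent carbon metabolism, 11 rose and 2 fell, against 12 rose and 2 fell adjusted over the list alone, with Nnmt (1.80) and Gnmt (1.68) among the rises and Csad (-1.59) and Mthfd1l (-3.27) the falls. Methionine cycle genes had a median of 0.48 (adjusted p = 0.000191, adjusted p = 0.133 with an estimated correlation). Among 40 genes of the urea cycle and amino acid breakdown, 14 rose and 2 fell, and 14 rose and 2 fell adjusted over the list alone, with Cps1 (1.47) and Oat (1.49) among the rises. Amino acid breakdown genes had a median of 0.38 (adjusted p = 0.000341, adjusted p = 0.157 with an estimated correlation).

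Several lists without a list call had members called in both directions. Within bile acid transport, Abcb11, the export pump for bile salts, rose from 235 ± 30.9 to 461 ± 73.2 CPM, and within the growth hormone list Igfbp2, a binding protein for insulin-like growth factors, rose from 45.8 ± 10.5 to 349 ± 148 CPM while Fst, the activin antagonist follistatin, fell from 5.04 ± 1.93 to 0.690 ± 0.475 CPM. For these uncalled lists, here and in the other comparisons, the counts are of members that rose and that fell, those in parentheses are adjusted over the list alone and p is that of the list test. Bile acid transport and FXR signalling had 6 and 5 of 20 (6 and 5, adjusted p = 0.584, median -0.25, mean 0.29, test directed higher). The growth hormone axis and hepatokines had 8 and 4 of 23 (8 and 7, adjusted p = 0.527, median 0.14, mean -0.15, test directed higher). Acute phase proteins had 10 and 6 of 32 (10 and 6, adjusted p = 0.163, median 0.14, mean -0.01, test directed higher). Lipoproteins and sterol export had 8 and 4 of 26 (10 and 4, adjusted p = 0.264). The unfolded protein response had 6 and 3 of 29 (6 and 3, adjusted p = 0.527). NRF2 targets had 5 and 5 of 23 (5 and 5, adjusted p = 0.646, median 0.03, mean -0.15, test directed lower). Fatty acid oxidation and ketogenesis had 4 and 5 of 37 (4 and 5, adjusted p = 0.783, median 0.02, mean -0.09, test directed lower). Glucocorticoid-induced genes had 3 and 5 of 20 (3 and 5, adjusted p = 0.527). Iron handling had 4 and 3 of 23 (7 and 8, adjusted p = 0.961, median 0.07, mean -0.15, test directed lower). The circadian clock had 2 and 3 of 22 (2 and 3, adjusted p = 0.334). Glucose metabolism and insulin signalling had 3 and 0 of 25 (2 and 0, adjusted p = 0.972, median -0.08, mean 0.01, test directed higher). Quiescent stellate cells had 2 and 2 of 17 (2 and 3, adjusted p = 0.945, median -0.10, mean 0.03, test directed lower). Antigen presentation and dendritic cells had 0 and 0 of 11 (0 and 0, adjusted p = 0.945). Cholangiocytes and progenitors had 1 and 1 of 17 (1 and 1, adjusted p = 0.961). Adipocyte markers had 2 and 1 of 7 (2 and 1, adjusted p = 0.646, median 0.34, mean -0.06, test directed lower). The clock list passed without the 3 acinar libraries or those 3 and WM 25 (adjusted p = 0.0424 and 0.0371).

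In edgeR's quasi-likelihood test, 1666 genes were higher and 1443 lower in RYGB than in Sham. Of these, 712 and 671 changed by at least 1 on the log2 scale. Without the 3 acinar libraries 1244 and 877 stayed called, and after the GC and length correction 1222 and 967. Library totals moved the median of all genes by -0.35 and gave 754 higher and 3534 lower, and limma-voom gave 2598 lower. Library totals also gave medians of 0.19, 0.36, -0.84, -0.88, -0.52, 0.16, 0.30, 0.27, -0.84 and 0.019 for the endothelial, erythrocyte, fat synthesis, interferon, lipid droplet, methionine cycle, pericentral, periportal, recruited macrophage and amino acid breakdown lists, in that order.

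Under calorie restriction, list calls with the preset correlation were higher than in Sham for male-biased (17 of 20 rose), respiratory (36 of 45) and cholesterol genes (14 of 25) and Kupffer (12 of 20) and endothelial markers (15 of 23). They were lower for matrix (20 of 41 fell), lipid droplet (11 of 24) and fat synthesis genes (14 of 28). None of these calls held (adjusted p = 0.0603 to 0.305 with an estimated correlation). Hsd3b5 rose from 0.167 ± 0.251 to 190.3 ± 102 CPM (log2 fold change 10.05 ± 0.75, adjusted p = 2.2e-10). Serpina1e, an antitrypsin of the male-biased set, rose from 61.4 ± 56.1 to 3910.0 ± 3399.7 CPM (log2 fold change 5.99 ± 0.63, adjusted p = 6.23e-08). Cidea, a lipid droplet protein, fell from 44.5 ± 41.3 to 0.958 ± 0.667 CPM (log2 fold change -5.55 ± 0.62, adjusted p = 1.63e-07). Sprr1a had 2 counts over all WM libraries against 2088 over Sham, 893-fold lower with an exact 95% interval, for counting error only, of 247 to 7375 (adjusted p = 1.26e-10).

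Other genes with the largest rises were Slco1a1 (log2 fold change 6.04, adjusted p = 1.98e-08), Clec2h (log2 fold change 4.91, adjusted p = 1.34e-10) and Enho, which encodes the peptide adropin, at 48.0 ± 27.1 CPM in WM and 2.82 ± 0.903 CPM in Sham (log2 fold change 4.08 ± 0.34, adjusted p = 1.91e-09). Falls of that rank were those of Cyp2b13 (log2 fold change -6.00, adjusted p = 5.88e-07), Ephb2 (log2 fold change -5.47, adjusted p = 1.17e-06) and Cyp2a4, a female-biased steroid hydroxylase (log2 fold change -5.40, adjusted p = 8.31e-06). Each of the 10 lay beyond the Sham median in 8 of 8 WM libraries. Cidec fell from 59.8 ± 28.1 to 1.80 ± 1.14 CPM and Fgf21 fell from 5.41 ± 1.47 to 0.983 ± 0.687 CPM (adjusted p = 4.34e-08 and 4.73e-05). Cyp7a1 did not pass (log2 fold change -0.24, adjusted p = 0.704). Nor did Cyp8b1 at 286 ± 345 CPM in WM and 416 ± 189 in Sham (log2 fold change -0.54, adjusted p = 0.348). WM 25 had 1128 CPM and the steepest slope on GC (9.14, next 4.63 in RYGB 18). Without it Cyp8b1 fell (log2 fold change -1.32, adjusted p = 0.00236). It also fell under limma-voom, after the GC and length correction and without the 3 acinar libraries and WM 25 (adjusted p = 0.00154, 0.0307 and 0.00101).

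Of 20 male-biased liver genes, 17 rose and 0 fell, while 17 rose and 0 fell adjusted over the list alone, with the peroxisomal hydrolase Nudt7 up from 107 ± 41.6 to 479 ± 134 CPM. Male-biased genes had a median of 2.16 (adjusted p = 2.55e-12, adjusted p = 0.152 with an estimated correlation). Among 13 female-biased liver genes, 8 fell and 2 rose, and 9 fell and 2 rose adjusted over the list alone, with Gstm3 down from 167 ± 90.6 to 11.5 ± 9.43 CPM. Female-biased genes had a median of -1.69 (adjusted p = 0.000177, adjusted p = 0.278 with an estimated correlation). For the 45 nuclear genes of oxidative phosphorylation, 36 rose and 0 fell, against 40 rose and 0 fell adjusted over the list alone, with Atp5h up from 135 ± 43.8 to 377 ± 73.1 CPM and Uqcrq of complex III up from 833 ± 183 to 2104 ± 656 CPM. Respiratory genes had a median of 0.86 (adjusted p = 1.08e-14, adjusted p = 0.0603 with an estimated correlation). After the GC and length correction the respiratory median was 0.47, with 26 of 45 higher, and under library totals it was 0.54. Of 25 genes of cholesterol synthesis and uptake, 14 rose and 1 fell, while 14 rose and 2 fell adjusted over the list alone, with the sterol isomerase Ebp up from 208 ± 24.5 to 519.6 ± 116 CPM, Cyp51 up from 81.9 ± 19.2 to 222 ± 33.5 CPM and Hmgcs1 the 1 that fell. Cholesterol genes had a median of 0.76 (adjusted p = 2.86e-05, adjusted p = 0.278 with an estimated correlation). Among 41 genes of matrix and activated stellate cells, 20 fell and 0 rose, and 22 fell and 0 rose adjusted over the list alone, led by Col1a1 (-3.88), Col1a2 (-2.89) and Col3a1 (-2.23). Matrix genes had a median of -1.03 (adjusted p = 2.29e-09, adjusted p = 0.146 with an estimated correlation). For the 24 genes of lipid droplets and fatty acid uptake, 11 fell and 0 rose, against 11 fell and 0 rose adjusted over the list alone, with Cd36 (-2.52), Plin4 (-3.93) and Plin2 (-0.95) among them. Lipid droplet genes had a median of -0.52 (adjusted p = 7.3e-06, adjusted p = 0.0603 with an estimated correlation), against -0.86 after the GC and length correction. Of 28 genes of fatty acid and triglyceride synthesis, 14 fell and 2 rose, while 15 fell and 2 rose adjusted over the list alone, with the acyltransferase Mogat1 down from 9.53 ± 2.88 to 1.14 ± 0.432 CPM and the elongase Elovl5 down from 1637 ± 271 to 441 ± 208 CPM. Fat synthesis genes had a median of -0.72 (adjusted p = 0.000243, adjusted p = 0.305 with an estimated correlation).

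Among 20 Kupffer cell markers, 12 rose and 0 fell, and 16 rose and 0 fell adjusted over the list alone, with Fcna up from 6.50 ± 3.10 to 34.5 ± 11.4 CPM and Nr1h3, the oxysterol receptor LXR alpha, up from 70.4 ± 13.9 to 158 ± 57.7 CPM. Kupffer markers had a median of 1.18 (adjusted p = 6.5e-06, adjusted p = 0.278 with an estimated correlation). For the 23 endothelial markers, 15 rose and 0 fell, against 16 rose and 0 fell adjusted over the list alone, with the water channel Aqp1 up from 19.9 ± 13.6 to 82.8 ± 28.8 CPM and Clec4g, a lectin of sinusoidal endothelium, up from 11.3 ± 7.33 to 43.4 ± 16.5 CPM. Endothelial markers had a median of 0.92 (adjusted p = 1.2e-05, adjusted p = 0.305 with an estimated correlation). Of 12 erythrocyte markers, 8 rose and 0 fell, while 8 rose and 0 fell adjusted over the list alone, with the beta globins Hbb-bs up from 1073 ± 339 to 3268 ± 1922 CPM and Hbb-bt up from 225 ± 97.8 to 724 ± 489 CPM. Erythrocyte markers had a median of 0.81 (adjusted p = 0.002, adjusted p = 0.163 with an estimated correlation). Among 27 markers of recruited and lipid-associated macrophages, 11 fell and 2 rose, and 12 fell and 3 rose adjusted over the list alone, with Anxa2 (-3.10), Mmp12 (-3.95) and Gpnmb (-3.97) among the falls. Recruited macrophage markers had a median of -0.73 (adjusted p = 0.00116, adjusted p = 0.387 with an estimated correlation). For the 29 cell cycle genes, 11 fell and 1 rose, against 11 fell and 1 rose adjusted over the list alone, with Ccnd1 (-1.54) and Cenpf (-2.43) among the falls and Ccne1 (1.71) the rise. Cell cycle genes had a median of -1.07 (adjusted p = 0.00105, adjusted p = 0.32 with an estimated correlation). Of 40 genes of the urea cycle and amino acid breakdown, 13 rose and 1 fell, while 16 rose and 1 fell adjusted over the list alone, with Agxt (1.30) among the rises and Gldc (-1.05) the fall. Amino acid breakdown genes had a median of 0.42 (adjusted p = 0.0109, adjusted p = 0.353 with an estimated correlation). The call was lost under library totals (adjusted p = 0.0526), and the median was 0.27 under limma-voom, 0.23 after the GC and length correction, 0.21 without the 3 acinar libraries and WM 25 and 0.24 without WM 25. Among 20 pericentral hepatocyte markers, 10 rose and 1 fell, and 10 rose and 1 fell adjusted over the list alone, with Cyp2e1 (1.61) among the rises and the ammonium transporter Rhbg the fall (-1.50). Pericentral markers had a median of 0.54 (adjusted p = 0.0122, adjusted p = 0.377 with an estimated correlation). This list did not pass without Sham 2 (adjusted p = 0.0571). None of the 14 lists called in WM vs Sham passed with an estimated correlation.

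Several lists had many members called in both directions and no list call. Within bile acid transport, Slc10a2 (-1.86) and Slc51b (-2.13) fell, while Slc10a1, the sodium-dependent uptake transporter for bile acids, rose from 112 ± 31.3 to 328 ± 64.9 CPM. Among acute phase proteins the fibrinogen chains Fga (0.74) and Fgg (0.65) rose, while the lipocalins Orm3 and Lcn2 fell from 23.0 ± 10.9 to 1.85 ± 1.81 CPM and from 36.1 ± 29.9 to 2.85 ± 2.27 CPM. Clock output genes Bhlhe41 (2.84), Dbp (1.89) and Per2 (1.12) rose and the clock activators Arntl (-2.03), Npas2 (-2.40) and Clock (-1.32) fell. Bile acid transport and FXR signalling had 2 and 10 of 20 (2 and 11, adjusted p = 0.0947). Acute phase proteins had 9 and 11 of 32 (9 and 11, adjusted p = 0.254). The circadian clock had 7 and 4 of 22 (7 and 4, adjusted p = 0.331). CAR and PXR targets had 7 and 7 of 29 (7 and 8, adjusted p = 0.683). The methionine cycle had 8 and 6 of 26 (10 and 6, adjusted p = 0.0566). Bile acid synthesis had 6 and 0 of 15 (6 and 0, adjusted p = 0.0813). Periportal markers had 8 and 1 of 21 (8 and 1, adjusted p = 0.117). Lipoproteins and sterol export had 10 and 3 of 26 (10 and 3, adjusted p = 0.171). Fatty acid oxidation and ketogenesis had 6 and 10 of 37 (7 and 10, adjusted p = 0.391). Glucose metabolism and insulin signalling had 5 and 4 of 25 (5 and 4, adjusted p = 0.813). The growth hormone axis and hepatokines had 6 and 7 of 23 (7 and 7, adjusted p = 0.683). NRF2 targets had 2 and 6 of 23 (2 and 6, adjusted p = 0.113). The unfolded protein response had 8 and 2 of 29 (8 and 2, adjusted p = 0.337). The interferon response had 2 and 5 of 30 (2 and 5, adjusted p = 0.394, median 0.28, mean 0.07, test directed lower). Iron handling had 2 and 1 of 23 (1 and 1, adjusted p = 0.454). Glucocorticoid-induced genes had 4 and 7 of 20 (6 and 7, adjusted p = 0.641, median 0.01, mean -0.40, test directed lower). Lymphocyte markers had 3 and 0 of 17 (3 and 0, adjusted p = 0.113). Antigen presentation and dendritic cells had 0 and 0 of 11 (0 and 0, adjusted p = 0.683). Cholangiocytes and progenitors had 2 and 4 of 17 (2 and 4, adjusted p = 0.401). Quiescent stellate cells had 1 and 3 of 17 (0 and 3, adjusted p = 0.478). Adipocyte markers had 0 and 2 of 7 (0 and 2, adjusted p = 0.0813).

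The methionine cycle list passed without Sham 3, WM 1, WM 7, WM 9, WM 13 or WM 27 (adjusted p = 0.0227 to 0.0474), and also with no low-count filter or with the Gm42418 share as a covariate (adjusted p = 0.0367 to 0.0406). Lymphocyte markers passed under library totals, without WM 1 or without WM 27 (adjusted p = 0.0104, 0.0428 and 0.0412). Adipocyte markers passed in a fit of the 2 groups alone or after the GC and length correction (adjusted p = 0.0112 and 0.0211). NRF2 targets, directed lower, passed after the GC and length correction (adjusted p = 0.0163). Acute phase proteins, directed lower, passed after the GC and length correction (adjusted p = 0.041). Bile acid transport, directed lower, passed without the 3 acinar libraries and WM 25 (adjusted p = 0.0499). Bile acid synthesis passed without Sham 6 (adjusted p = 0.0493). Interferon response genes passed as lower without WM 13 (adjusted p = 0.000859, median log2 fold change -0.48).

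In edgeR's quasi-likelihood test, 2161 genes were higher and 1964 lower in WM than in Sham. Of these, 989 and 902 changed by at least 1 on the log2 scale. After the GC and length correction 1490 and 1295 stayed called. Scaling by library totals alone moved the median of all genes by -0.33 and gave 1049 higher and 3637 lower. That scaling also gave medians of 0.41, 0.57, 0.46, -0.82, 0.22 and 0.07 for the cholesterol, endothelial, erythrocyte, lipid droplet, pericentral and amino acid breakdown lists, in that order.

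Against Sham, 2459 genes were called in the same direction in RYGB and in WM, 1354 upward and 1105 downward, and 5 genes in opposite directions. The 5 were Id1, Slc45a3, Slc41a2, Hmgcs1 and Slc51b, which were named after their values were seen. Slc51b, a subunit of the bile acid exporter of the basolateral membrane, was higher in RYGB than in Sham and lower in WM than in Sham (log2 fold changes 1.59 and -2.13), and Id1, a target of bone morphogenetic protein signalling, went the other way (-1.38 and 0.91). Across the 13121 tested genes, which are not independent replicates, the log2 fold changes correlated at r = 0.849. Both comparisons share the Sham libraries, and 20 simulations of unchanged groups against shared controls, with 12644 to 12740 genes tested, gave a mean r of 0.493 and a mean of 0.05 genes in the same direction. Independent lists of these lengths would share 274 genes upward and 216 downward. With the 8 Sham libraries split into separate sets of 4 libraries, the medians over 70 values were r = 0.734 and 1250 genes on the same 13121 genes, and r = 0.586 and 1222.5 genes on the 14123 that the filter kept with these sets. The covariance was 0.562 against 0.0532 simulated, a difference of 0.509, and 0.524 with separate sets of Sham libraries on the same genes.

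**Figure D1:**
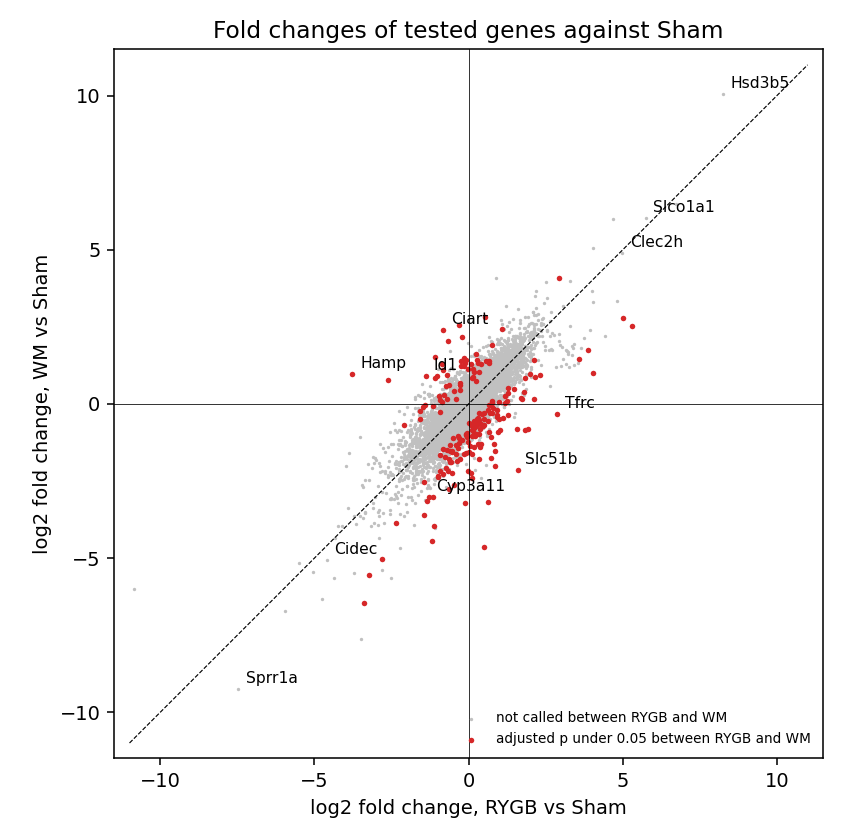
Log2 fold change of each tested gene in RYGB vs Sham (horizontal axis) against WM vs Sham (vertical axis), with the genes called between RYGB and WM in red and the others in grey, and a dashed line where both are equal. Hsd3b5 and Slco1a1 lie at the upper right and Cidec at the lower left, while Hamp, Id1, Tfrc and Slc51b lie away from the dashed line, and the leftmost point is Cyp2b13, whose fitted value against no count in RYGB is not a bound.

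At matched weight, in RYGB against WM livers, Hamp, which encodes the iron hormone hepcidin, fell from 606 ± 425 to 22.7 ± 38.5 CPM (log2 fold change -4.74 ± 0.91, adjusted p = 0.00332), and Tfrc, the transferrin receptor that takes up iron, rose from 10.9 ± 5.25 to 99.3 ± 60.2 CPM (log2 fold change 3.19 ± 0.42, adjusted p = 5.19e-05). Slc51b rose from 0.366 ± 0.168 to 4.85 ± 2.12 CPM (log2 fold change 3.72 ± 0.40, adjusted p = 1.7e-06). Arntl, which encodes the clock activator BMAL1, rose from 1.20 ± 0.826 to 8.95 ± 7.16 CPM (log2 fold change 2.89 ± 0.51, adjusted p = 0.00138), and Per2, a clock repressor, fell from 25.6 ± 13.4 to 6.68 ± 3.08 CPM (log2 fold change -1.94 ± 0.37, adjusted p = 0.0031).

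**Figure D2:**
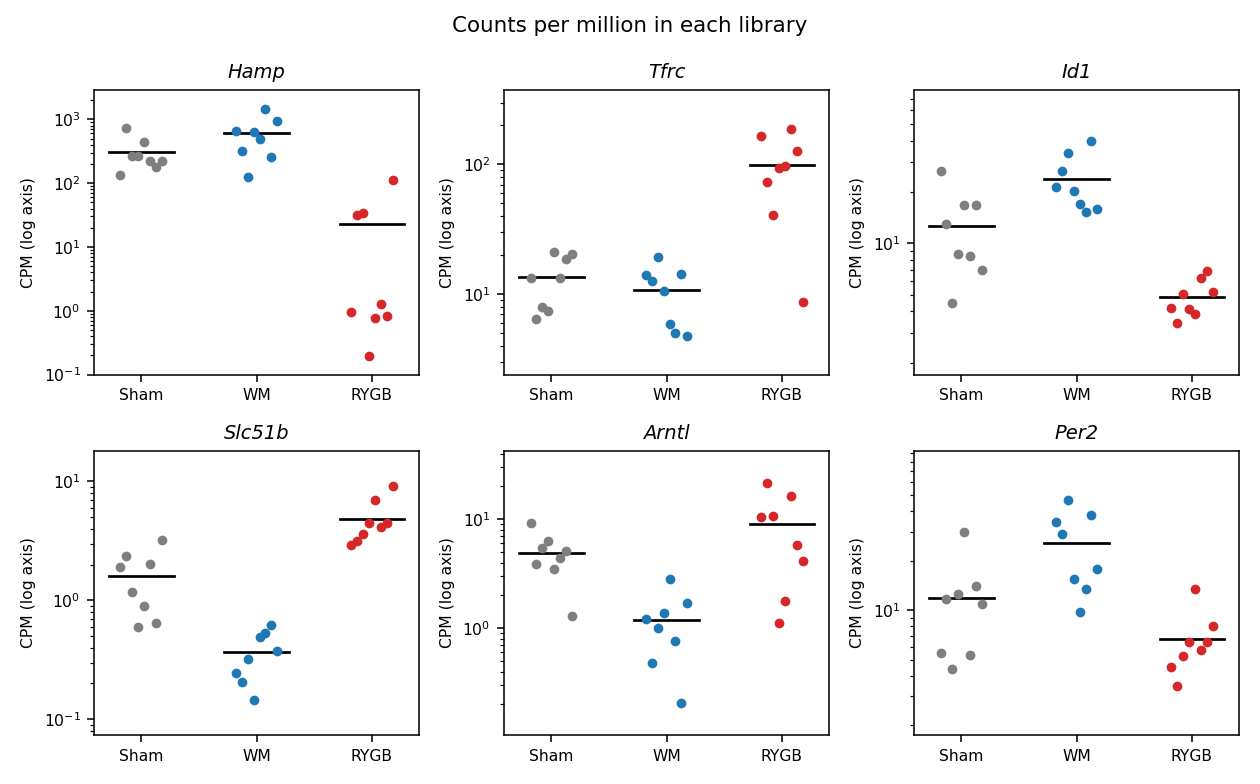
CPM of Hamp, Tfrc, Id1, Slc51b, Arntl and Per2 in each of the 8 libraries of Sham, WM and RYGB, on log axes, with each point 1 library and each line the group mean. RYGB 29 has the highest Hamp (111 CPM) and the lowest Tfrc (8.78 CPM) of the 8 RYGB libraries, and Arntl in RYGB 18 and RYGB 19 lies within the range of WM.

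Other large rises were those of Tff3 (log2 fold change 2.77, adjusted p = 0.00368), of Slc39a4, a zinc importer, from 12.4 ± 11.9 to 69.3 ± 39.3 CPM (log2 fold change 2.48 ± 0.48, adjusted p = 0.00389), and of Cfd, the protease adipsin (log2 fold change 2.67, adjusted p = 0.023). The largest falls also took in Ciart, a repressor of the clock (log2 fold change -3.22, adjusted p = 0.0143), Bhlhe41, another (log2 fold change -2.29, adjusted p = 0.0127), and the heat shock gene Hspa1b, from 36.9 ± 19.9 to 5.10 ± 2.10 CPM (log2 fold change -2.85 ± 0.54, adjusted p = 0.0031). Id1 fell from 23.7 ± 8.89 to 4.86 ± 1.20 CPM (log2 fold change -2.29 ± 0.29, adjusted p = 2.87e-05). Of the 12 genes named so far, Tfrc and Cfd lay beyond the WM median in 7 of 8 RYGB libraries and the others in 8 of 8. Fgf21, Cidec and Cyp7a1 did not pass (log2 fold changes 0.35, 0.46 and 0.15, adjusted p = 0.851, 0.829 and 0.958). Cyp8b1 did not pass (log2 fold change 0.77, adjusted p = 0.516), and it rose without WM 25 (log2 fold change 1.56, adjusted p = 0.00631), under limma-voom (adjusted p = 0.0131) and without the 3 acinar libraries and WM 25 (adjusted p = 0.0370). Cfd did not pass in a fit of the 2 groups alone, under limma-voom, under limma-trend or without RYGB 10 (adjusted p = 0.0765, 0.373, 0.109 and 0.0612).

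Of 23 iron genes, 3 rose, 3 fell and 17 did not pass, and 4 rose and 7 fell adjusted over the list alone. The rises were Tfrc (3.19), Hfe2 (0.95) and Slc11a2 (0.73) and the falls Hamp (-4.74), Id1 (-2.29) and Atoh8 (-1.91), where Hfe2 encodes the hepcidin regulator hemojuvelin, Slc11a2 an iron importer and Atoh8 a transcription factor. As a list they did not pass (median -0.28, list test adjusted p = 0.117). Among 22 clock genes, 5 fell and 2 rose, and 13 fell and 4 rose adjusted over the list alone, with Arntl (2.89) and Clock (0.91) the rises and Per1 (-1.38), Per2 (-1.94), Bhlhe40 (-0.92), Bhlhe41 (-2.29) and Ciart (-3.22) the falls. Clock genes had a median of -0.74 (adjusted p = 3.74e-05, adjusted p = 0.0391 with an estimated correlation). For the 25 genes of cholesterol synthesis and uptake, 5 rose and 0 fell, against 12 rose and 0 fell adjusted over the list alone. Hmgcs1, the synthase at the head of the pathway, rose from 149.9 ± 71.1 to 551 ± 211 CPM and the cyclase Lss rose from 10.6 ± 3.05 to 28.5 ± 6.80 CPM. Cholesterol genes had a median of 0.56 (adjusted p = 1.43e-14, adjusted p = 0.0391 with an estimated correlation). Of 20 genes of bile acid transport and FXR signalling, 4 rose and 0 fell, while 5 rose and 1 fell adjusted over the list alone. Slc10a2, the apical sodium-dependent transporter, rose from 20.4 ± 8.37 to 56.6 ± 16.4 CPM, and the others were Slc51b (3.72), Abcb11 (0.91) and Slco1a4 (1.00). Bile acid transport genes had a median of 0.29 (adjusted p = 1.91e-06, adjusted p = 0.0391 with an estimated correlation). Among 24 genes of lipid droplets and fatty acid uptake, 5 rose and 0 fell, and 7 rose and 0 fell adjusted over the list alone. Cd36, a fatty acid receptor, rose from 30.9 ± 15.8 to 64.7 ± 8.83 CPM and Plin5, a droplet coat protein, rose from 46.2 ± 15.4 to 89.9 ± 24.6 CPM, beside Lpl (1.18), Cidea (2.31) and Fabp4 (1.63). Markers of adipocytes, another tissue, were called higher too (median 0.46, adjusted p = 0.14 with an estimated correlation), and share Fabp4. Lipid droplet genes had a median of 0.23 (adjusted p = 2.96e-05, adjusted p = 0.0391 with an estimated correlation). For the 29 targets of CAR and PXR, 3 rose and 0 fell, against 5 rose and 0 fell adjusted over the list alone. Cyp3a11 rose from 156 ± 72.1 to 508 ± 151 CPM, Cyp2c29 rose from 478 ± 113 to 1058 ± 166 CPM, and the other was Cyp2c55 (2.32). Drug metabolism genes had a median of 0.37 (adjusted p = 3.76e-07, adjusted p = 0.0454 with an estimated correlation), against 0.16 without the 3 acinar libraries and 0.57 without WM 25. The clock, cholesterol, bile acid transport, lipid droplet and drug metabolism lists were the 5 of 17 called in RYGB vs WM that also passed with an estimated correlation.

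Of 32 acute phase proteins, 2 rose and 0 fell, while 5 rose and 0 fell adjusted over the list alone, the called ones over all genes being Fgl1 (1.58) and Orm3 (2.15). Acute phase proteins had a median of 0.32 (adjusted p = 3.44e-08, adjusted p = 0.0851 with an estimated correlation). Among 30 interferon response genes, 1 fell and 0 rose, and 1 fell and 0 rose adjusted over the list alone, the 1 over all genes being Gbp3 (-1.90). Interferon genes had a median of -0.69 (adjusted p = 0.000731, adjusted p = 0.554 with an estimated correlation). No list call was made without WM 13 (adjusted p = 0.792), and the median was -0.36 under limma-voom, -0.30 under limma-trend and -0.043 without WM 13. For the 21 periportal markers, 2 rose and 0 fell, against 4 rose and 0 fell adjusted over the list alone. Cdh1 rose from 18.3 ± 3.83 to 45.0 ± 14.4 CPM and the lyase Etnppl rose from 69.6 ± 16.3 to 125 ± 38.3 CPM. Periportal markers had a median of 0.18 (adjusted p = 0.000404, adjusted p = 0.135 with an estimated correlation), against 0.31 under limma-voom, 0.30 without the 3 acinar libraries and WM 25 and 0.29 without WM 13. Etnppl did not pass under library totals, without WM 1 or without RYGB 15 (adjusted p = 0.0984, 0.0523 and 0.0592). Of 26 genes of the methionine cycle, 3 rose and 0 fell, while 3 rose and 0 fell adjusted over the list alone. Among them the methyltransferase Bhmt rose from 512 ± 185 to 1120.3 ± 122 CPM, beside Cth (0.93). Methionine cycle genes had a median of 0.07 (adjusted p = 0.0199, adjusted p = 0.366 with an estimated correlation). They did not pass without the 3 acinar libraries, WM 9, WM 13, WM 27, RYGB 18 or RYGB 19 (adjusted p = 0.243, 0.0642, 0.0638, 0.0509, 0.0709 and 0.064). Over the settings and with 1 library left out the median was -0.018 to 0.18. Among 23 genes of the growth hormone axis and hepatokines, 2 rose and 0 fell, and 4 rose and 0 fell adjusted over the list alone. Igfbp1 rose from 21.6 ± 7.96 to 94.1 ± 78.7 CPM and Stat5b, which carries the growth hormone signal, rose from 27.2 ± 4.49 to 45.0 ± 11.4 CPM. Growth hormone axis genes had a median of 0.03 (adjusted p = 0.0227, adjusted p = 0.0851 with an estimated correlation), while the median was -0.005 under library totals. The call was lost without the 3 acinar libraries, those 3 and WM 25, WM 13, RYGB 18 or RYGB 19 (adjusted p = 0.133, 0.0804, 0.0673, 0.0552 and 0.0516). Over the settings and with 1 library left out the median was -0.046 to 0.14. For the 7 adipocyte markers, 2 rose and 0 fell, against 3 rose and 0 fell adjusted over the list alone, the called ones over all genes being Cfd and the fatty acid binding protein Fabp4. Adipocyte markers had a median of 0.46 (adjusted p = 0.012, adjusted p = 0.14 with an estimated correlation). This list did not pass without any 1 of WM 9, WM 27, RYGB 18 or RYGB 19 (adjusted p = 0.0529 to 0.0796), nor with no low-count filter, under limma-voom, without the 3 acinar libraries or without those 3 and WM 25 (adjusted p = 0.0589 to 0.292), and the median was 0.13 with no low-count filter, 0.13 under limma-voom, 0.25 under limma-trend, -0.06 without the 3 acinar libraries, -0.030 without those 3 and WM 25, 0.25 without WM 9, 0.30 without WM 27 and 0.039 without RYGB 19. Fabp4 passed at log2 fold change 1.63, adjusted p = 0.048 and in 12 of 36 settings, with adjusted p from 0.0208 to 0.169 over them.

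Of 13 female-biased genes, 1 rose and 0 fell, while 4 rose and 1 fell adjusted over the list alone, the 1 over all genes being Atp6v0d2 (2.39). Female-biased genes had a median of 0.71 (adjusted p = 0.00494, adjusted p = 0.366 with an estimated correlation). No list call was made without the 3 acinar libraries, those 3 and WM 25, WM 1 or RYGB 19 (adjusted p = 0.176, 0.0618, 0.0932 and 0.0958), and the median was 0.46 under the 1 CPM filter, 0.45 in a fit of the 2 groups alone, 0.30 without the 3 acinar libraries and 0.27 to 0.46 without any 1 of Sham 5, Sham 6, Sham 14, Sham 23, WM 1, WM 13, WM 25, WM 27, RYGB 10 or RYGB 19. Holding Cyp2b13 at its bound left that median at 0.71 and moved the mean from 0.37 to 0.49. Among 28 fat synthesis genes, 2 rose and 0 fell, and 6 rose and 1 fell adjusted over the list alone, the called ones over all genes being Elovl5 (1.28) and Acss2 (0.97). Fat synthesis genes had a median of 0.17 (adjusted p = 0.012, adjusted p = 0.467 with an estimated correlation). They did not pass without the 3 acinar libraries, those 3 and WM 25, RYGB 18 or RYGB 19 (adjusted p = 0.322, 0.164, 0.0529 and 0.0919), and the median was 0.37 under limma-voom, 0.027 without the 3 acinar libraries, 0.30 without WM 25, 0.08 without RYGB 19 and 0.27 without RYGB 22. For the 41 matrix genes, 0 rose and 0 fell, against 0 rose and 0 fell adjusted over the list alone. Matrix genes had a median of 0.21 (adjusted p = 0.012, adjusted p = 0.494 with an estimated correlation). The call was lost without any 1 of WM 1, WM 9, WM 27, WM 30, RYGB 18 or RYGB 19 (adjusted p = 0.0516 to 0.0864), and without the 3 acinar libraries or without those 3 and WM 25 (adjusted p = 0.0618 to 0.18), and the median was 0.14 without those 3 and WM 25, 0.11 without WM 9, 0.12 without WM 27, 0.07 without WM 30 and 0.11 without RYGB 11. Of 23 NRF2 targets, 0 rose and 0 fell, while 4 rose and 0 fell adjusted over the list alone. NRF2 targets had a median of 0.14 (adjusted p = 0.0215, adjusted p = 0.227 with an estimated correlation). This list did not pass without the 3 acinar libraries, those 3 and WM 25, WM 9, RYGB 18 or RYGB 19 (adjusted p = 0.133, 0.053, 0.0957, 0.0529 and 0.0571), and the median was 0.07 under limma-voom and 0.07 without RYGB 11. Among 27 markers of recruited macrophages, 2 rose and 0 fell, and 3 rose and 0 fell adjusted over the list alone, the called ones over all genes being Atp6v0d2 (2.39) and Lpl (1.18). Recruited macrophage markers had a median of -0.01 (adjusted p = 0.0455, adjusted p = 0.615 with an estimated correlation), while the test was directed higher and the mean was 0.14. No list call was made without any 1 of Sham 14, Sham 16, Sham 17, WM 1, WM 9, WM 25, WM 27, WM 30, RYGB 11, RYGB 18, RYGB 19, RYGB 22 or RYGB 28 (adjusted p = 0.0511 to 0.223), nor with no low-count filter, under limma-voom, without the 3 acinar libraries or without those 3 and WM 25 (adjusted p = 0.0693 to 0.151). Over the settings and with 1 library left out the median was -0.11 to 0.17. For the 23 endothelial markers, 0 fell and 0 rose, against 0 fell and 0 rose adjusted over the list alone. Endothelial markers had a median of -0.21 (adjusted p = 0.049, adjusted p = 0.625 with an estimated correlation). They did not pass without any 1 of Sham 6, Sham 17, WM 7, WM 9, WM 13, WM 20, WM 25, WM 30, RYGB 10, RYGB 18, RYGB 19, RYGB 22 or RYGB 29 (adjusted p = 0.0512 to 0.249), nor under RLE, under library totals, after the GC and length correction, with the Gm42418 share as a covariate, without the 3 acinar libraries or without those 3 and WM 25 (adjusted p = 0.0526 to 0.254), and the median was -0.38 without RYGB 11.

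Other lists were not called between RYGB and WM, the first 6 and the last of them called in both comparisons with Sham. Oxidative phosphorylation had 0 and 0 of 45 (0 and 0, adjusted p = 0.486). Male-biased genes had 1 and 0 of 20 (2 and 5, adjusted p = 0.106). Kupffer markers had 0 and 1 of 20 (0 and 1, adjusted p = 0.275). Erythrocyte markers had 0 and 0 of 12 (0 and 0, adjusted p = 0.242). The cell cycle had 0 and 0 of 29 (0 and 2, adjusted p = 0.537). The urea cycle and amino acid breakdown had 0 and 0 of 40 (0 and 0, adjusted p = 0.283). Bile acid synthesis had 0 and 0 of 15 (0 and 0, adjusted p = 0.275). Fatty acid oxidation and ketogenesis had 1 and 0 of 37 (2 and 0, adjusted p = 0.242). Lipoproteins and sterol export had 0 and 1 of 26 (1 and 2, adjusted p = 0.443, median 0.02, mean -0.05, test directed lower). Glucose metabolism and insulin signalling had 0 and 2 of 25 (3 and 2, adjusted p = 0.6). The unfolded protein response had 0 and 1 of 29 (0 and 3, adjusted p = 0.458, median 0.03, mean -0.12, test directed lower). Glucocorticoid-induced genes had 0 and 1 of 20 (3 and 4, adjusted p = 0.804, median -0.11, mean 0.04, test directed lower). Quiescent stellate cells had 1 and 0 of 17 (1 and 0, adjusted p = 0.244). Antigen presentation and dendritic cells had 0 and 0 of 11 (0 and 0, adjusted p = 0.275). Lymphocyte markers had 0 and 0 of 17 (0 and 0, adjusted p = 0.458). Cholangiocytes and progenitors had 0 and 0 of 17 (1 and 0, adjusted p = 0.0696). Pericentral markers had 1 and 0 of 20 (3 and 1, adjusted p = 0.0686). Male-biased genes, directed lower, passed without WM 7, WM 9, WM 30, RYGB 18 or RYGB 28 (adjusted p = 0.0114 to 0.0351), and also with no low-count filter or in a fit of the 2 groups alone (adjusted p = 0.0253 to 0.0408). Pericentral markers passed without WM 25, RYGB 11, RYGB 15, RYGB 22 or RYGB 28 (adjusted p = 0.0293 to 0.046), and also in a fit of the 2 groups alone or with the Gm42418 share as a covariate (adjusted p = 0.0353 to 0.042). Cholangiocyte markers passed in a fit of the 2 groups alone, under limma-trend, after the GC and length correction, without WM 7, without WM 20 or without RYGB 28 (adjusted p = 0.0462, 0.0424, 0.0478, 0.0157, 0.0337 and 0.0466). Lymphocyte markers passed without WM 20 (adjusted p = 0.0128).

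**Figure D3:**
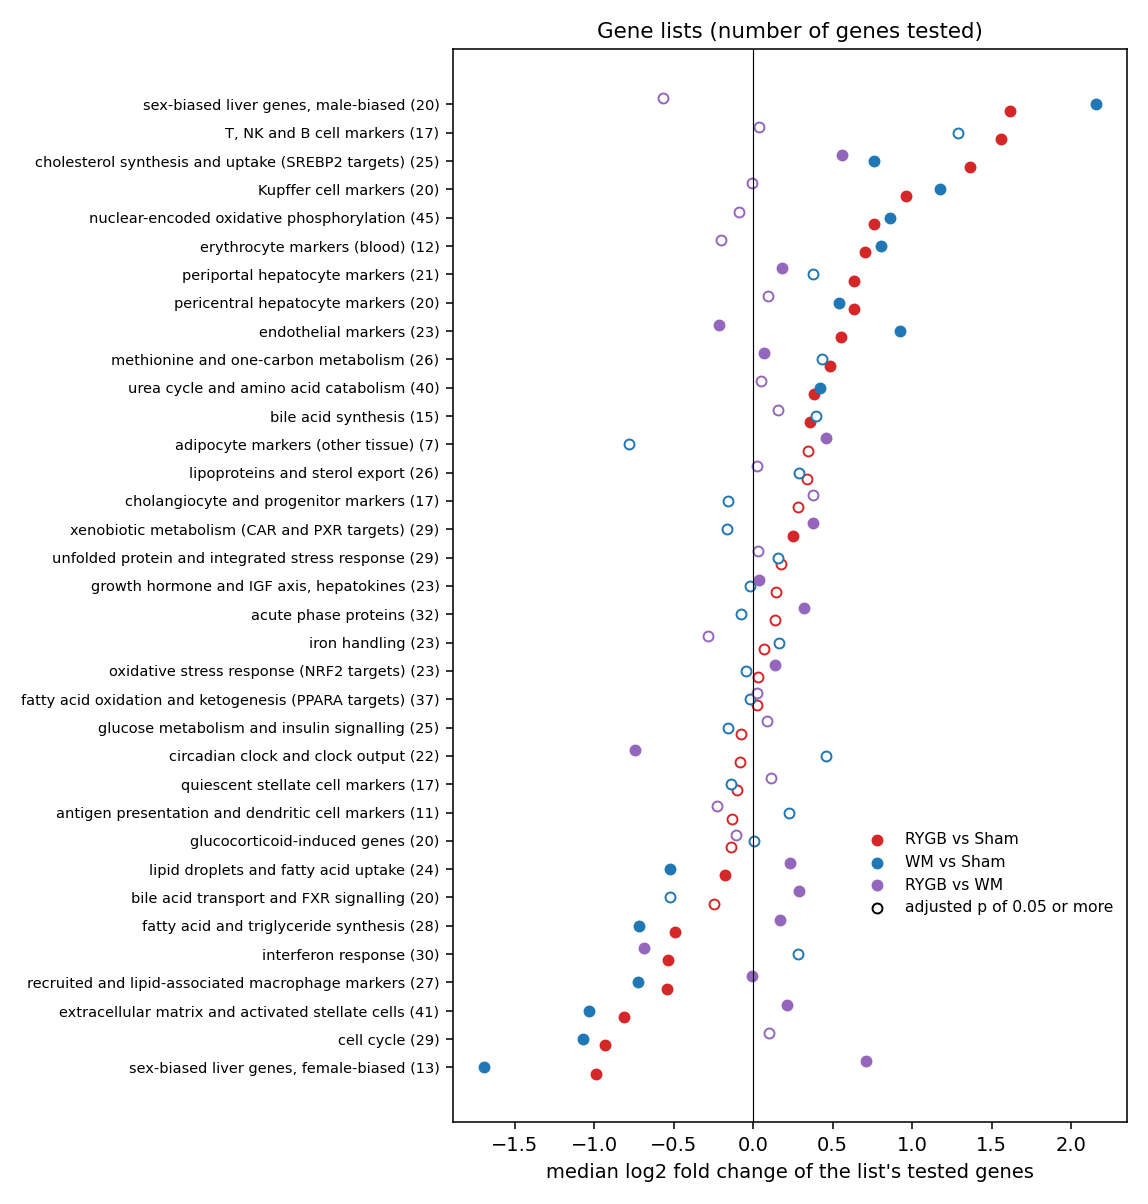
Median log2 fold change (horizontal axis) of the tested genes of 35 lists (vertical axis, with the number tested) in RYGB vs Sham in red, WM vs Sham in blue and RYGB vs WM in purple, where filled points have an adjusted p under 0.05 in the list test with its preset correlation. Male-biased, cholesterol and respiratory genes lie to the right in both comparisons with Sham and matrix genes to the left, while under library totals the called medians of bile acid synthesis and of drug metabolism genes in RYGB vs Sham and of growth hormone axis genes in RYGB vs WM turn negative.

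Directly compared by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 139 genes were higher and 57 lower in RYGB than in WM. Of the 139, 69 were lower in WM than in Sham with no call in RYGB vs Sham, 30 were higher in RYGB vs Sham alone and 20 were lower in both. Of the 57, 29 were higher in WM vs Sham alone and 16 lower in RYGB vs Sham alone. DESeq2 gave 228 higher and 133 lower, the GC and length correction 231 and 101, limma-voom 88 lower and a fit of the 2 groups alone 27 lower. The count of lower genes was 36 without WM 1, 30 without WM 27, 29 without RYGB 10 and 36 without RYGB 15, and the lists called were 10 without RYGB 18, 8 without RYGB 19 and 8 without the 3 acinar libraries.

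Some named genes have close relatives in the genome, and how reads matching several genes were counted is not given in the sources used here. Values of Hamp, Hbb-bs, Hbb-bt, Serpina1e, Hspa1b, Cyp2b13, Cyp2a4, Cyp4a12b, Cyp3a11, Cyp2c29, Orm3, Gstm3 and the Mup genes are uncertain to that extent. Use of strand in the counting is not given either, so overlapping and antisense genes cannot be told apart. The labels number the samples without tying each to 1 mouse, so that p-values measure only the spread between these libraries, which may be technical. List members given only with a log2 fold change were, where the rule for named genes does not take them, chosen after their values were seen. Markers of neutrophils, pancreas, intestine and muscle or skin had 4, 1, 2 and 3 tested members and were not tested as lists.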

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

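The search for outlying libraries and the test of whether RYGB 29 belongs to the Sham group were set before the results were seen, and the other tests in this part were chosen only after the result was seen. In 21 of 236 sets of 8 libraries, from 71 genes and 8 measures, the highest or lowest library stood apart by Dixon's criterion, and chance picks out about 1 in 20 sets. RYGB 19 had Hsd3b5 at 1.79 CPM (median of RYGB 59.6), Slco1a1 at 73.7 CPM (244), Sprr1a at 0.448 CPM (0) and Fst at 0 CPM (0.555). Among genes called without the library itself, RYGB 19 lay nearer the other RYGB libraries than WM at 56.6% of 212 and RYGB 11 at 70.9% of 179, and RYGB 22 and RYGB 11 nearer them than Sham at 65.8% of 3132 and 71.2% of 3094, the lowest shares of the 8. Sham 17 had Alb at 21500 CPM (median of Sham 33600) and Fgf21 at 2.44 CPM (5.59), and RYGB 18 had Fgf21 at 0.132 CPM (median of RYGB 1.3). Summed pancreas acinar transcripts, which lie outside the genes tested, stood at 1890 CPM in Sham 17, 2520 CPM in RYGB 18 and 2870 CPM in RYGB 19, against a median of 0.636 CPM in Sham. WM 25 had Cyp8b1 at 1130 CPM (median of WM 180) and Fst at 0.0756 CPM (1.16). RYGB 10 had Elovl5 at 1910 CPM (median of RYGB 985) and Plin5 at 148 CPM (81). Cfd was lowest in RYGB 15 at 0.314 CPM (median of RYGB 31.3) and in Sham 16 at 2.99 CPM (median of Sham 9.08). In Sham, Elovl3 stood at 32.4 CPM in Sham 3 (median 60.6), Mmp12 at 31.8 CPM in Sham 2 (5), Hspa1b at 33.1 CPM in Sham 14 (2.78), Bhlhe41 at 0.108 CPM in Sham 23 (1.52) and the share of counts on Gm42418 at 26.5% in Sham 6 (8.81%). In WM, Atp5h was lowest in WM 9 at 221 CPM (median 388) and Cyp2e1 in WM 20 at 3170 CPM (4680).

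Iron genes differed between RYGB and WM, with Hamp, Id1 and Atoh8 lower and Tfrc, Hfe2 and Slc11a2 higher in RYGB, while RYGB 29 had the highest Hamp and the lowest Tfrc of its group. A wrong label of RYGB 29 is argued against, since it lay nearer the other RYGB libraries than WM at 82.3% of 164 genes called without it, and nearer them than Sham at 84.0% of 2789 genes. Reads divided between Hamp and its copy Hamp2 are argued against by their sum, which was 57.7 ± 117 CPM in RYGB and 749 ± 484 CPM in WM (log2 ratio -3.70, exact permutation p = 0.000466, n = 8 each). The GC and length correction left 6 of the 6 genes called, but, picked as called, they cannot decide on trends. An effect of bypass surgery as against calorie restriction stays open and untested, since these libraries hold no measure of iron.

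Clock genes differed between RYGB and WM, and the list had an adjusted p of 2.93e-05 after the GC and length correction, which argues against those trends as the cause. The mean log2 CPM of Arntl, Npas2, Clock and Nfil3 and that of 9 output genes, among them Per2, Dbp and Ciart, moved against each other within the 8 RYGB libraries (Pearson's r = -0.978, exact permutation p = 2.48e-05, the smallest it can give, and Spearman's rho = -1, p = 4.96e-05, adjusted p = 0.000149 for both over 6 tests). Without the 2 libraries farthest from the median r was -0.957, and within Sham and WM r was -0.803 (exact permutation p = 0.0111, adjusted p = 0.0166) and -0.538 (p = 0.171, adjusted p = 0.197). Libraries taken at different times of day or after feeding would move in this way, while a shift shared by a group would not spread its libraries. For the difference between the groups the 2 cannot be told apart, because the labels give no time of collection or feeding.

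Genes of oxidative phosphorylation were higher in RYGB and in WM than in Sham (adjusted p = 0.0402 and 0.0603 with an estimated correlation). The GC and length correction took the medians from 0.76 to 0.46 in RYGB and from 0.86 to 0.47 in WM. Adjusted p was then 5.97e-10 and 3.18e-08 with the preset correlation. The correction cannot tell a technical trend from a rise of short transcripts. A higher share of hepatocytes stays open, since Kupffer cells can gain share beside them. Pericentral hepatocyte markers had medians of 0.63 and 0.54, and activated stellate genes of -0.81 and -1.03. Kupffer cell markers had 12 of 20 higher in each and 0 lower. Their medians were 0.96 and 1.18 (adjusted p = 0.219 and 0.278 with an estimated correlation). The scaling between libraries as the whole cause is argued against by medians of 0.43 and 0.54 under library totals. An effect of weight loss on these genes stays open and untested, and the share of mitochondrial counts was 8.22% in RYGB and 9.10% in WM against 9.25% in Sham (adjusted p = 0.77 and 0.904).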

How the results depend on the processing

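The settings with library totals, the GC and length correction, Gm42418 as a covariate or the pancreas-bearing libraries left out, separate Sham libraries on the same genes, and all settings of the list tests other than the estimated correlation and the members called by DESeq2, were chosen only after the result was seen. Of 1274 values of named genes under the alternatives, with the lowest and highest of the libraries left out in turn, 1254 kept their side of the threshold, 13 lost a call, 7 gained one and 0 turned direction with a call. Of the 1254, 17 uncalled values turned their sign, those of Cyp7a1 in each comparison, Cyp8b1 in RYGB vs Sham and Cidec in RYGB vs WM. Of single lists under 12 settings, libraries left out in turn not counted, 391 values kept their side in RYGB vs Sham, 27 lost a call and 2 gained one, against 397, 15 and 8 in WM vs Sham and 376, 37 and 7 in RYGB vs WM. Leaving out each of the 24 libraries in turn, of 840 values each, 6 lost a call and 0 gained one in RYGB vs Sham, 1 and 10 in WM vs Sham and 52 and 14 in RYGB vs WM. The members of a list called by DESeq2 came to over 1.5 times those of edgeR, or fewer by as much, for 11 lists in RYGB vs WM and for none of 35 in the other comparisons.

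Requiring an absolute log2 fold change of 1 left 712 of 1666 higher and 671 of 1443 lower genes in RYGB vs Sham, 989 of 2161 and 902 of 1964 in WM vs Sham and 92 of 139 in RYGB vs WM, by construction. Scaling by library totals moved the median of all genes by -0.35 in RYGB vs Sham, -0.33 in WM vs Sham and -0.02 in RYGB vs WM, and gave 754 higher and 3534 lower genes (17.6% higher, against 53.6% with TMM) and 1049 and 3637 (22.4% against 52.4%) in the comparisons with Sham. Limma-voom gave 2598 lower genes in RYGB vs Sham, 88 lower in RYGB vs WM and 3731 genes called in both comparisons with Sham in the same direction, against 2459. In RYGB vs WM, DESeq2 gave 228 higher and 133 lower genes, the GC and length correction 231 and 101, and a fit of the 2 groups alone 27 lower. For these settings other than the fold minimum the cause was not tested.

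With an estimated correlation, 2 lists passed in RYGB vs Sham (20 with the preset one), 0 in WM vs Sham (14) and 5 in RYGB vs WM (17). Random splits calling 0 genes gave up to 20, 20 and 23 lists in that order with the preset one. Its calls alone can thus arise by chance. In RYGB vs WM 8 lists passed without the 3 pancreas-bearing libraries and 9 also without WM 25, against 8 without RYGB 19 alone. The correlation of fold changes was 0.741 with no low-count filter. With separate Sham libraries, which leave fewer libraries in each comparison, it was 0.734 with 1250 genes shared on the same genes, and 0.586 with 1222.5 shared on the 14123 genes that the filter then kept, so that the filter accounts for part of the fall in the correlation.

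Leaving out 1 library at a time gave 1450 to 1835 higher and 1129 to 1679 lower genes in RYGB vs Sham, 1943 to 2261 and 1607 to 2046 in WM vs Sham, and 107 to 180 and 29 to 77 in RYGB vs WM. Lists called numbered 8 to 19 in RYGB vs WM. No paired analysis was possible because no sample number is shared between groups. With 8 libraries per group, changes of 1.5-fold were mostly missed in simulation, so that genes without a call may still differ by that much.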

Other observations

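The tests of other splits of the libraries and the genes of this part were chosen only after the result was seen. Several genes outside the lists separated RYGB from WM in edgeR's quasi-likelihood test. Insig2, which encodes a protein that retains the sterol sensor in the endoplasmic reticulum, stood at 369 ± 69.0 CPM in Sham, 157 ± 44.4 CPM in WM and 365 ± 117 CPM in RYGB (n = 8 each, RYGB vs WM log2 fold change 1.22 ± 0.20, adjusted p = 0.000568). Acmsd, an enzyme that diverts tryptophan breakdown from NAD synthesis, stood at 6.89 ± 1.98, 7.76 ± 3.42 and 22.9 ± 6.84 CPM in the same order (RYGB vs WM log2 fold change 1.56 ± 0.24, adjusted p = 0.00042). Dio1, the deiodinase that activates thyroid hormone, stood at 208 ± 50.0, 147 ± 51.1 and 68.9 ± 19.1 CPM (RYGB vs WM log2 fold change -1.09 ± 0.20, adjusted p = 0.00281). Lipa, the lysosomal acid lipase, stood at 472 ± 102, 219 ± 37.0 and 379 ± 67.1 CPM (RYGB vs WM log2 fold change 0.80 ± 0.16, adjusted p = 0.0041). Tubb2a, a beta tubulin, stood at 216 ± 33.1, 35.0 ± 8.17 and 156 ± 53.1 CPM (RYGB vs WM log2 fold change 2.15 ± 0.20, adjusted p = 1.91e-07).

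The 16 libraries of each comparison were also divided at random into other sets of 8 and 8, with 100 splits per comparison, the real one included. The limit for the share of splits as large was 0.05, not adjusted over these tests. In RYGB vs Sham 3109 genes outnumbered all other splits (highest 1363, 1 of 100 splits as large). So did 4125 in WM vs Sham (highest other 190, 1 of 100). In RYGB vs WM (196, 3 of 100) 2 other splits gave more, 250 and 306, so chance is not excluded. For lists, RYGB vs Sham lay under the limit (20, equalled by 1 other split, 2 of 100). WM vs Sham (14, highest other 20, 24 of 100) and RYGB vs WM (17, highest other 23, 6 of 100) did not.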
